A study of Bacillus subtilis subsp. subtilis str. 168 with 4 samples.

How the data were processed

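The series compared a wild-type Bacillus subtilis 168 strain with a double mutant of ccpN and yqfL, with 2 macroarrays for each. Per the labels' protocols, cells were grown in glucose minimal medium (10 g/L) to an OD600 of 0.5, and 2 µg of total RNA was copied into cDNA labelled with 33P and hybridised. Groups and replicate numbers were taken from the sample titles. The design text gives separate days, RNA preparations and array sets for the 2 comparisons, so replicates are separate cultures as far as the labels say it.

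The deposited values are intensities on a linear scale, 1 per feature, called raw per the file headers. Whether background was subtracted, spots averaged or features filtered is not given in the sources used here, nor is the scanner software. The lowest values were 0, on 2, 5, 14 and 0 of the 4107 features of wild-type arrays 1 and 2 and mutant arrays 1 and 2. The means were 35474, 37155, 31670 and 31018 in the same order. The brightest probe on every array, for galK, held 12.2%, 5.09%, 15.6% and 4.63% of the signal, and the 10 brightest held 28.8%, 14.0%, 31.8% and 11.0%.

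The series' value table held the same intensities divided by a constant per array, with means close to 1 and medians of 0.2194 and 0.3104 for its wild-type columns and 0.4297 and 0.2196 for its mutant columns. It is linear and not centred per gene. In it the 2 mutant columns are exchanged relative to the deposited files of the single samples, with 100% of features at 1 ratio (tolerance 0.001) only when crossed. Which of the mutant numberings is right is not given in the sources used here. The single-sample files were used, and the exchange does not touch a fit without pairing.

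Gene names came from the platform annotation given with the data. Of 4107 features, 3862 had 1 gene symbol, 32 had several and 213 were unnamed here, and 3848 of the single-symbol probes were found by gene ID in a reference gene table (assembly ASM904v1), which was used only for current names and for neighbours. Older symbols in the lists were matched to current ones after the names on the array had been seen, without regard to values. For 13 symbols there was more than 1 probe, each tested separately, and in 6 of them the probes differed in sign. No feature was marked as blank or control, so all 4107 were tested.

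Each array was scaled to a common median, values under the 5th percentile of positive values of the array (1103, 2007, 751 and 2843 before scaling, in the order above) were set to it, and log2 was taken. Values at that floor are called at the detection floor, and 618 features had one on at least 1 array. A fold against a strain at the floor on both arrays is a lower bound. The normexp correction foreseen for arrays with a background column did not apply. Strains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment at 0.05, over all features and over each fixed list alone. The residual degrees of freedom were 2, the prior degrees of freedom 3.06 and the prior SD 0.93. The median over features of the SD between replicates was 0.72 in the wild type and 0.84 in the mutant, and the median SE of a log2 fold change was 0.92 (0.58 with the block). The fold changes give the antilog of differences between mean log2 values.

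The groups, tests, gene lists, alternatives and the rule for genes to be named were fixed before the data were examined. The 30 lists were the deleted genes, CcpN targets, neighbours of the deletion, glycolysis, pyruvate and anaplerosis, overflow metabolism, citric acid cycle, pentose phosphate pathway, ATP synthase, respiration, arginine breakdown, synthesis of arginine, branched-chain, aromatic, histidine and sulfur amino acids, purines and pyrimidines, nitrogen, carbon catabolite control, ribosomal proteins, fatty acid synthesis, sigma B, heat shock, Fur and iron, motility, competence, sporulation, and the PBSX and SPβ prophages. The 28 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Lists are said below to rise or fall by camera at the preset correlation alone. Among these, the estimated correlation ranged from -0.07 (histidine) to 0.35 (SPβ). A preset below the true correlation makes camera's p-value too small, and that p-value does not measure agreement between replicates. Of the neighbours, 5 of 6 genes were measured, and of the targets 2 of 3. Genes named were all measured members of the first 3 lists, the 3 members of each list with the smallest unadjusted p, and the 10 genes in each direction with the largest change among those past the threshold. Where fewer than 5 passed, the last part took in their place, as values only, the 10 with the smallest unadjusted p among features at least 2-fold different without overlap of the strains.

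The replicate numbers were treated as pairing the arrays, since the design text puts the 2 comparisons on different days with different array sets and both strains in each. Deviations from the strain means correlated at 0.688 between arrays with the same number. With the value table's numbering this becomes -0.688 by construction, so it is no second check. Pearson's r between strains was 0.928 and 0.689 for arrays with the same number, and 0.450 and 0.520 for arrays with different numbers. If equal numbers mark the same day, this favours the numbering of the single-sample files. The fit with the replicate number as a block (residual degrees of freedom 1, prior degrees of freedom 6.11) was an alternative. Within-replicate fold changes are given for some genes and lists only. Where a pooled value stands alone, the replicates may differ in size or sign.

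The fits were tested on simulated data with 200 of 4107 features changed and a further 50 raised 2-fold as a list. Noise was drawn independently for each feature from the blocked fit's spread, and both strains had the same difference between replicates. The fit without a block recovered 0 of the 200 at 2-fold, 8-fold and 32-fold, and the blocked fit recovered 0%, 82% and 100%, with 0, 4 and 3 false calls. In the measured data the blocked fit missed gapB and pckA at 40.2-fold and 48.9-fold (limma adjusted p = 0.0729 for both). Simulated recovery is therefore no measure of what the blocked fit could detect here. Unchanged features had an unadjusted p under 0.05 in 0.0519% to 0.0778% of cases without the block and in 4.23% to 4.93% with it, so the unblocked fit is conservative when replicates share a day. A simulated list of 50 members raised 2-fold was found by camera at the preset correlation in every run and at an estimated correlation in none (adjusted p from 0.244 to 0.991), and 0 of 20 unchanged lists were called. The unchanged lists were random features that varied independently. They do not show how often camera wrongly calls lists whose members vary together.

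The alternatives were the block, quantile normalization, scaling to total signal, cyclic loess, no scaling, no floor, a floor at the 25th percentile, a filter on the dimmest 25% of features, a pseudocount, a trended robust variance, the value table and leaving out each array. The blocked fit with cyclic loess and the block with the value table's numbering were added after the data were seen. As a comparison added once the list medians were known, lists were also set against 10000 random lists of the same size (2000 for lists not weighed in the closing part), matched over 20 bins of mean brightness, and the limits given are those leaving out the lowest and highest 2.5% of them. Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.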

Results

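Transcript levels across the chromosome of Bacillus subtilis 168 were measured in the wild type and in a double mutant of ccpN and yqfL. CcpN is a repressor of gluconeogenic genes during growth on glucose, and yqfL is the gene next to it on the chromosome, named ppsR in the reference gene table used here. Both strains were harvested in exponential growth, at an OD600 of 0.5, from minimal medium with 10 g/L glucose. Each strain had 2 macroarrays hybridised with 33P-labelled cDNA, from cultures compared on separate days with separate RNA preparations. Every array gave an intensity for 4107 features, with a median of 7780 and 11699 on wild-type arrays 1 and 2 and of 7028 and 13338 on mutant arrays 1 and 2. Arrays with the same replicate number resembled each other more than arrays of the same strain. Across the 4107 features, which are not independent replicates, Pearson's r of the log2 values was 0.928 between the replicate 1 arrays and 0.689 between the replicate 2 arrays, against 0.524 between the wild-type arrays and 0.483 between the mutant arrays. The small number of arrays limits the precision of every value below.

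Transcripts of both deleted genes were strongly reduced in the mutant. The ccpN signal (probe 1272) fell 7.93-fold, from a log2 intensity of 14.28 ± 0.10 in the wild type to 11.29 ± 0.14 in the mutant (SD, n = 2 each). The ppsR (yqfL) signal (probe 1271) fell 11.7-fold, from 14.20 ± 0.30 to 10.65 ± 0.85 (SD, n = 2 each), and was at the detection floor on 1 of the 2 mutant arrays, that of replicate 1. Every mutant array lay below its wild-type partner, by 7.06-fold and 8.91-fold for ccpN and by at least 20.5-fold and by 6.66-fold for ppsR in replicates 1 and 2. The log2 fold changes were -2.99 (SE 0.72) and -3.55 (SE 0.82). Both passed limma's test with Benjamini-Hochberg adjustment over the list alone (adjusted p = 0.00888 for each) but not over all features (adjusted p = 1.0). Without wild-type replicate 2 neither passed over the list alone (limma adjusted p = 0.0579), and whether the probes lie inside the deleted parts is not given in the sources used here. The folds depended on how dim values were handled, with 4.71-fold for ccpN and 4.47-fold for ppsR under a floor at the 25th percentile, 3.58-fold and 4.14-fold with a pseudocount, and for ppsR 18.3-fold without a floor and 7.72-fold and 17.7-fold without mutant replicates 1 and 2.

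The genes around the deletion did not pass the test. The log2 fold change was 0.05 (SE 1.31) for yqxD, 0.01 (SE 0.74) for dnaG, which encodes DNA primase, and -0.48 (SE 0.85) for sigA, which encodes the main sigma factor. The glycyl-tRNA synthetase genes glyQ and glyS had -0.26 (SE 0.87) and -0.65 (SE 0.77). None of these 5 genes passed over all features or adjusted over the list alone (limma adjusted p = 0.993 for each), and the median of the list was -0.26 (camera adjusted p = 0.584, and 0.744 with an estimated correlation). At these errors a change of several fold in any of them was not detectable.

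The known CcpN targets gapB and pckA gave the largest increases on the array. Transcript of gapB, which encodes the glyceraldehyde-3-phosphate dehydrogenase used in gluconeogenesis, rose 40.2-fold (probe 2949), from 10.86 ± 0.23 in the wild type to 16.18 ± 0.44 in the mutant (log2 intensity, SD, n = 2 each). Transcript of pckA, which encodes phosphoenolpyruvate carboxykinase, rose 48.9-fold (probe 3419), from 12.54 ± 0.23 to 18.16 ± 0.79 (SD, n = 2 each). The rise was 55.7-fold and 28.9-fold for gapB and 64.1-fold and 37.3-fold for pckA in replicates 1 and 2. The log2 fold changes were 5.33 (SE 0.75) and 5.61 (SE 0.81), and both genes passed limma's test adjusted over the list alone (adjusted p = 0.000904 for each, and 3.55e-05 with the replicate number as a block). Over all features neither did (limma adjusted p = 1.0, and 0.0729 for both with the block). Where dim values were raised the folds were smaller, with 17.8-fold for gapB under a floor at the 25th percentile, and with 12.9-fold for gapB and 29.0-fold for pckA with a pseudocount, all still past the test over the list alone. The third target on the list, the small RNA SR1, was not analysed here. These targets were listed from prior knowledge of CcpN, which may in part rest on arrays such as these.

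**Figure D1:**
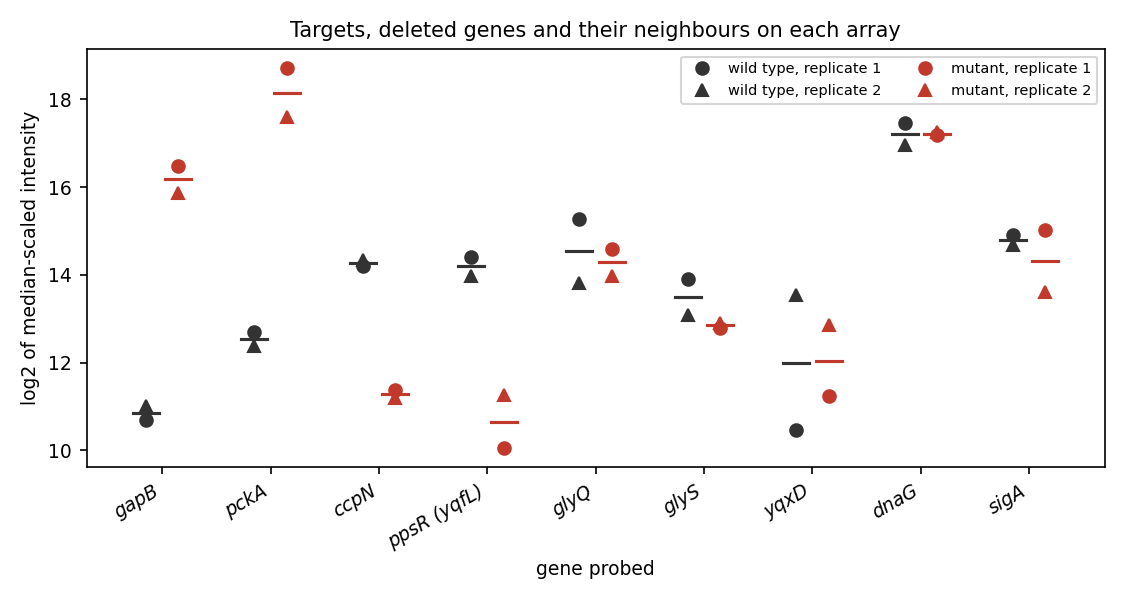
Log2 of median-scaled intensity (vertical axis) on each of the 4 arrays for the CcpN targets, the deleted genes and the genes around the deletion (horizontal axis), with wild type in black, mutant in red, circles for replicate 1, triangles for replicate 2 and a bar at each strain's mean. The mutant means of gapB and pckA, 16.18 and 18.16, lie above both wild-type arrays, and those of ccpN and ppsR, 11.29 and 10.65, lie below them.

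Across the genome, the genes with the clearest higher values in the mutant besides gapB and pckA were mostly sporulation genes. The fixed rule for genes to be named, applied to the 359 features that differed at least 2-fold with no overlap of the strains (166 higher and 193 lower), took the 10 in each direction with the smallest unadjusted p, as values. Among the higher ones, sspG, sspL and sspJ encode small acid-soluble spore proteins, cotW and cotO encode spore coat proteins, and spoIIIAG and spoIIIAH encode parts of the channel between the mother cell and the forespore. Their log2 fold changes were 3.22 (SE 0.86) for sspG, 3.04 (SE 0.95) for cotW, 2.86 (SE 0.77) for cotO, 2.80 (SE 0.76) for sspL, 2.74 (SE 0.84) for spoIIIAG and 2.43 (SE 0.73) for spoIIIAH. The wild type was at the detection floor on 1 of 2 arrays for sspG and sspL, and on both for sspJ, which was therefore at least 5.20-fold higher in the mutant, taking that floor as the level of the wild type. The sizes depend on how dim values are treated and on single arrays. With a higher floor, with a pseudocount or with any 1 array left out, the log2 fold changes ranged from 1.93 to 3.87 for sspG, 2.09 to 4.001 for cotW, 2.16 to 3.30 for cotO, 1.64 to 3.14 for sspL, 1.85 to 3.28 for spoIIIAG, 1.64 to 2.66 for spoIIIAH and 0.95 to 2.64 for sspJ. Probe 2181, unnamed here, had 3.47 (SE 0.93), and ranged from 2.58 to 4.36 under the same alternatives.

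Among the lower ones besides the deleted genes, 3 belong to the SPβ prophage. These were dpoL, which encodes a phage DNA polymerase, at -3.71 (SE 0.79), yoqU at -3.48 (SE 1.36) and yorC at -2.32 (SE 0.82). As the rule for naming them requires, they were lower in both replicates, by 8.16-fold and 20.9-fold for dpoL, 3.85-fold and 32.2-fold for yoqU and 5.36-fold and 4.62-fold for yorC. The others were cutJ at -2.17 (SE 0.86), the methionine transporter genes metN at -1.84 (SE 0.72) and metP at -1.74 (SE 0.72), aroB of the shikimate pathway at -1.80 (SE 0.77) and sirC of siroheme synthesis at -1.66 (SE 0.72). Under the same alternatives yoqU ranged from -5.28 to -1.67, dpoL from -4.16 to -2.83, yorC from -2.80 to -1.51 and cutJ from -2.85 to -0.91. None of these genes passed limma's test over all features, so the values carry no claim of change gene by gene. In all, 0 of 4107 features passed with limma and Benjamini-Hochberg adjustment, and 28 had an unadjusted p under 0.05. This fit leaves the difference between replicates in its error, and in simulation it recovered 0 of 200 changes of 32-fold. Its count of 0 therefore says little about how many genes changed. With the replicate number as a block the count was again 0, with 210 features at an unadjusted p under 0.05. In simulation 4.23% to 4.93% of unchanged features had such a p with the block, against 0.0519% to 0.0778% without it. The larger count is therefore not by itself a sign of more changes. The strains did not overlap for 801 features (19.5%). With the strain labels exchanged in replicate 2 the count was 650 (15.8%), and between the replicates it was 2656 (64.7%), while 4 arrays without any shared structure would give 33.3% by chance. With 2 arrays against 2, a permutation test of a single gene cannot give a two-sided p below 0.333. The median log2 fold change of all features was -0.09 with median scaling and 0.14 with scaling to total signal, so the list medians below are best read relative to that shift.

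**Figure D2:**
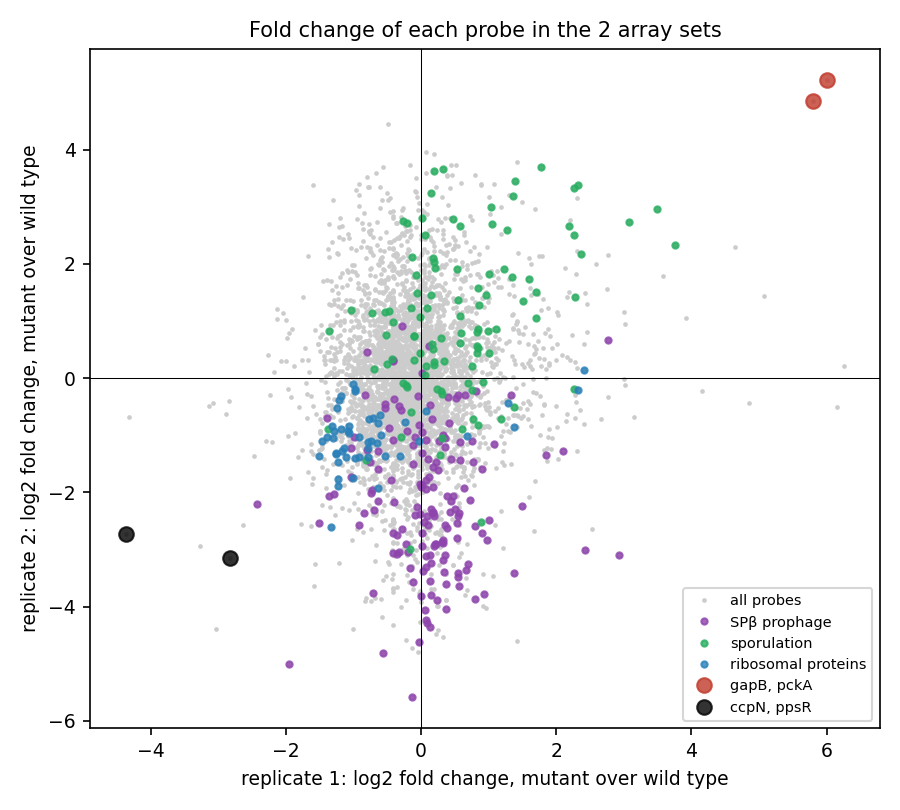
Log2 fold change of each of the 4107 probes, mutant over wild type, in the replicate 1 arrays (horizontal axis) and the replicate 2 arrays (vertical axis), each point a probe, with sporulation, ribosomal protein and SPβ prophage probes, the CcpN targets and the deleted genes in colour. The targets and the deleted genes lie far from 0 on both axes, SPβ probes spread downwards mainly on the vertical axis (medians 0.11 and -2.22), and the correlation over all probes is 0.098.

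Sporulation genes as a list rose in the mutant. Of 103 measured members, 87 were higher and 16 lower, with 59 higher in both replicates, and the median log2 fold change was 0.69, or 1.62-fold. The median was 0.34 in replicate 1, where 74 members were higher, and 0.98 in replicate 2, where 80 were. With limma's camera at its preset correlation the adjusted p was 1.61e-16, and with an estimated correlation the adjusted p was 0.661. Camera with an estimated correlation missed a simulated list of 50 members raised 2-fold in every run, so it cannot decide here or for the other lists. No single member passed over all features or adjusted over the list alone. With the replicate block, 5 members rose when adjusted over the list alone (limma adjusted p = 0.0421 for each), namely sspG, cotW, cotO, sspL and sspA. The last is named after its values were seen (log2 fold change 2.91, SE 1.10 in the fit without the block).

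Genes of the general stress response controlled by sigma B also rose as a list. Of 35 members, 29 were higher, 19 of them in both replicates, with a median log2 fold change of 0.57 (0.12 in replicate 1 and 0.91 in replicate 2). The camera adjusted p was 0.000208, and the adjusted p was 0.661 with an estimated correlation. The stress genes gspA, brxJ and gsiB had log2 fold changes of 1.85 (SE 1.09), 1.84 (SE 1.32) and 1.59 (SE 1.13), and no member passed on its own. The list did not pass without wild-type replicate 2 (camera adjusted p = 0.203) or without mutant replicate 1 (0.121), and its median lay above the upper limit for lists of matched brightness in replicate 2 (0.28) but just under it in replicate 1 (percentile 96.85).

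Ribosomal protein genes fell as a list. Of 50 members, 46 were lower, 44 of them in both replicates, and the median log2 fold change was -0.96, a 1.95-fold lower level. It was -0.98 in replicate 1 and -1.03 in replicate 2. The camera adjusted p was 1.97e-10 at the preset correlation of 0.01, and 0.661 at the estimated correlation of 0.163. Large-subunit protein genes headed the list, with log2 fold changes of -1.97 (SE 1.03) for rplM, -1.29 (SE 0.72) for rplQ and -1.25 (SE 0.73) for rplL. No member passed over all features or adjusted over the list alone. The size of the shift depended on scaling, with a median of -0.50 after cyclic loess and -0.58 after quantile normalization, both still past the threshold.

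Several biosynthetic pathways fell as lists by camera at its preset correlation. All 8 histidine synthesis genes were lower in both replicates, with a median log2 fold change of -1.22 and with -1.53 (SE 1.05) for hisA, -1.50 (SE 0.87) for hisF and -1.46 (SE 0.74) for hisG. The histidine list fell (camera adjusted p = 0.000461, and 0.661 with an estimated correlation). Of 24 genes of sulfur amino acid synthesis and uptake, 18 were lower (14 in both replicates), with a median of -0.46 (-0.85 in replicate 1, where 23 were lower, and -0.20 in replicate 2, where 14 were), led by metN, metP and sirC (camera adjusted p = 0.00356, and 0.680 with an estimated correlation). Of 16 purine synthesis and salvage genes, 15 were lower (11 in both replicates), with a median of -0.61, and with -1.48 (SE 0.79) for purH, -1.26 (SE 0.79) for xpt and -1.01 (SE 1.03) for purK (camera adjusted p = 0.0153, and 0.680 with an estimated correlation).

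All 8 arginine synthesis genes were lower (7 in both replicates), with a median of -0.78, and with -1.40 (SE 1.37) for argF, -1.04 (SE 0.77) for argH and -0.83 (SE 0.74) for argG (camera adjusted p = 0.0331, and 0.680 with an estimated correlation). Of 13 genes of aromatic amino acid synthesis, 12 were lower, but only 5 in both replicates. Their median was -0.36, with -0.90 in replicate 1 and 0.07 in replicate 2, and aroB, aroH, which encodes chorismate mutase, at -1.20 (SE 0.73) and aroF at -1.01 (SE 0.77) were at its head (camera adjusted p = 0.0260, and 0.680 with an estimated correlation). No member of these 5 lists passed on its own. Against random lists of matched brightness, the medians of the aromatic and purine lists lay inside the limits (-0.57 to 0.35 and -0.61 to 0.14), the purine list at the edge (percentile 2.55), and those of the histidine, sulfur and arginine lists lay below their lower limits of -0.71, -0.41 and -0.76. Within single replicates the histidine list lay below its limit in both, and the sulfur, arginine and aromatic lists in replicate 1 only. Leaving out 1 array ended the call of each list, with camera adjusted p of 0.138 for histidine (without mutant replicate 1) and 0.0690 (without wild-type replicate 2), 0.955 (wild-type replicate 1) and 0.502 (mutant replicate 2) for sulfur, 0.419 and 0.780 for purines, 0.848 and 0.780 for arginine, and 0.872 and 0.494 for aromatic amino acids, each pair without the same 2 arrays as for sulfur. Without wild-type replicate 1 camera's direction for the sulfur list turned upward. The aromatic list also lost its call without mutant replicate 1 (0.138), the purine list after cyclic loess (0.0587), and the arginine list after cyclic loess (0.0852), after quantile normalization (0.0587) and without the dimmest 25% of features (0.0544).

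Pyrimidine and branched-chain amino acid synthesis did not pass. The 8 pyrimidine genes had a median of -0.52, with 7 lower (camera adjusted p = 0.0793, and 0.744 with an estimated correlation), and with -1.43 (SE 0.79) for pyrE, -1.15 (SE 0.75) for pyrR and 0.86 (SE 0.98) for pyrD. The 10 branched-chain genes had a median of -0.03, which turned positive under quantile, total-signal and cyclic loess scaling (camera adjusted p = 0.696, and 0.901 with an estimated correlation). Among them ilvK had -0.77 (SE 0.76), leuD -0.51 (SE 0.73) and ilvC -0.37 (SE 0.76), the last also positive under quantile and cyclic loess scaling.

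In central carbon metabolism, genes for pyruvate conversion and anaplerosis fell as a list. The list as fixed also holds fbp, which belongs to neither process. Of 10 members, 9 were lower, all 9 in both replicates, with a median log2 fold change of -0.74. Subunits of pyruvate dehydrogenase led, with -1.05 (SE 0.73) for pdhB, -1.08 (SE 0.78) for pdhC and -0.89 (SE 0.73) for pdhD. The camera adjusted p was 0.0260, and the adjusted p was 0.661 with an estimated correlation. No member passed on its own, the median lay below the lower limit of -0.68 for lists of matched brightness (in replicate 1 but not in replicate 2 taken singly), and the list missed the threshold without any 1 of the 4 arrays (camera adjusted p from 0.129 to 0.460), after quantile normalization (0.0582) and after cyclic loess (0.0922).

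The other lists of central metabolism did not pass camera at the preset correlation. The values with an estimated correlation cannot decide, as said for sporulation. Glycolysis had a median of -0.53 over 13 genes, 9 of them lower (camera adjusted p = 0.287, and 0.732 with an estimated correlation), with -1.27 (SE 0.76) for ptsI, which encodes the general enzyme I of sugar phosphotransfer, -0.94 (SE 1.17) for pgm and -0.59 (SE 0.89) for pgi. The pentose phosphate pathway had a median of -0.32 with all 8 genes lower (0.501, and 0.744 with an estimated correlation), among them tal at -0.67 (SE 0.77), rpe at -0.53 (SE 0.99) and rpiB at -0.43 (SE 0.78). The citric acid cycle had a median of 0.12 over 11 genes (0.247, and 0.744 with an estimated correlation), with 1.63 (SE 0.81) for citB, which encodes aconitase, 1.07 (SE 1.16) for odhB and -0.60 (SE 0.74) for sdhC. The replicates disagreed for odhB, with 2.30 in replicate 1 and -0.17 in replicate 2. After cyclic loess the camera adjusted p of the citric acid cycle list was 0.0382, with a median of 0.52. The 9 genes of the overflow list, which covers acetate, acetoin and lactate metabolism, had a median of -0.32 (0.573, and 0.744 with an estimated correlation), with -0.79 (SE 0.79) for lctP, -0.61 (SE 0.83) for ackA and -0.32 (SE 0.83) for acuA.

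ATP synthase and the respiratory chain did not pass either. The 9 ATP synthase genes had a median of -0.33 (camera adjusted p = 0.584, and 0.744 with an estimated correlation), with -0.95 (SE 0.92) for atpC, -0.89 (SE 0.81) for atpG and 0.90 (SE 1.21) for atpF. The value of atpF was 2.36 in replicate 1 and -0.55 in replicate 2. The 24 respiratory genes had a median of -0.14, positive under total-signal scaling, while camera's direction was upward (0.822, and 0.900 with an estimated correlation). Among them qcrB had 0.71 (SE 0.74), and qoxA and qoxD of the quinol oxidase each had -1.09 (SE 1.13 and 1.09).

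Genes of the SPβ prophage as a list were lower in the mutant, mainly on the replicate 2 arrays as the single-sample files number them. The gene dpoL is not on the list, which was drawn up by gene name. Over 156 probes the median log2 fold change was -1.04, a 2.05-fold lower level, with 144 lower and 12 higher. In replicate 2 the median was -2.22, with 149 lower, and in replicate 1 it was 0.11, with 57 lower, so that 53 were lower in both. The median log2 intensity of the prophage was 12.97 and 14.58 on wild-type arrays 1 and 2 and 13.38 and 12.16 on mutant arrays 1 and 2. The camera adjusted p was 2.26e-15, and the adjusted p was 0.680 with an estimated correlation. No member passed on its own, and yorM, next in the list after yoqU and yorC, had -2.24 (SE 1.05). The list did not pass without wild-type replicate 2 (camera adjusted p = 0.203) or without mutant replicate 2 (0.0570). The defective prophage PBSX had a median of 0.04 over 33 probes (camera adjusted p = 0.686, and 0.900 with an estimated correlation), with -1.71 (SE 1.12) for xkdV, 1.29 (SE 0.89) for xkdU and -1.003 (SE 0.75) for xkdF. The values of xkdV and xkdU came mainly from replicate 2, with -3.29 and 2.07, against -0.13 and 0.50 in replicate 1.

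The remaining lists, on nutrient use, stress and development, did not pass camera, and no member of them passed limma's test over all features or adjusted over the list alone. Genes under carbon catabolite control had a median of 0.03 over 58 members (camera adjusted p = 0.866, and 0.918 with an estimated correlation), although the xylose and xylan genes xylA, xynP and xynB had -2.38 (SE 1.35), -2.24 (SE 1.60) and -1.95 (SE 0.94). These falls came mainly from replicate 2, with -4.18, -3.88 and -3.21, against -0.58, -0.60 and -0.68 in replicate 1. Nitrogen metabolism had a median of 0.21 over 17 genes (0.326, and 0.680 with an estimated correlation), with 1.17 (SE 0.76) for ureB and 0.91 (SE 0.92) for ureA, both urease subunits, and 0.77 (SE 0.84) for ansZ. Arginine breakdown had a median of 0.00 over 8 genes, negative after cyclic loess (0.837, and 0.900 with an estimated correlation), with 0.92 (SE 1.27) for rocB, -0.67 (SE 0.89) for rocR and -0.18 (SE 0.89) for rocA, the last positive under total-signal scaling. Fatty acid synthesis had a median of -0.29 over 11 genes (0.584, and 0.760 with an estimated correlation), with -0.80 (SE 0.73) for fabF, -0.61 (SE 0.90) for fabD and 0.68 (SE 1.05) for accD.

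Iron uptake genes under Fur had a median of -0.08 over 34 members, positive under total-signal scaling, while camera's direction was upward (camera adjusted p = 0.851, and 0.918 with an estimated correlation). Among them feuB had 1.28 (SE 0.97), pbtO -0.68 (SE 0.75) and fhuC -0.66 (SE 0.74). The value of feuB came mainly from replicate 2, at 2.43, against 0.14 in replicate 1. Heat shock genes had a median of -0.49 over 14 members (0.417, and 0.744 with an estimated correlation), with 1.24 (SE 0.86) for clpE, -1.08 (SE 0.76) for dnaJ and -0.88 (SE 0.82) for clpC. The value of clpE came mainly from replicate 1, at 2.31, against 0.17 in replicate 2. Motility genes had a median of -0.33 over 35 members, 27 of them lower (0.0793, and 0.680 with an estimated correlation), with 1.98 (SE 1.30) for fliK, -1.86 (SE 0.95) for fliR and -1.18 (SE 0.76) for fliF. Their sizes differed between replicates 1 and 2, with 3.01 and 0.94 for fliK, -0.49 and -3.22 for fliR, and -0.68 and -1.68 for fliF. Competence genes had a median of 0.14 over 22 members (0.247, and 0.744 with an estimated correlation), with 2.49 (SE 1.43) for ssbB, 1.49 (SE 1.57) for bdbC and 1.17 (SE 1.39) for nucA. These values came mainly from replicate 1, with 3.93, 2.997 and 1.80, against 1.06, -0.01 and 0.53 in replicate 2. Without wild-type replicate 1, bdbC and nucA turned negative, at -0.64 and -0.45. The competence median lay above the upper limit of 0.05 for lists of matched brightness, but the replicates differed, with 0.44 and 19 members higher in replicate 1 against -0.21 and 15 members lower in replicate 2, the latter inside its matched limits. The competence list turned to a median of -0.50 without wild-type replicate 1. It passed upward after cyclic loess (camera adjusted p = 0.0419) and without wild-type replicate 2 (0.000833). Pyrimidine synthesis and motility passed downward with a floor at the 25th percentile (0.0306 and 0.0353) and with a pseudocount (0.0193 and 0.0289), and pyrimidine synthesis also without wild-type replicate 2 (0.00825).

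**Figure D3:**
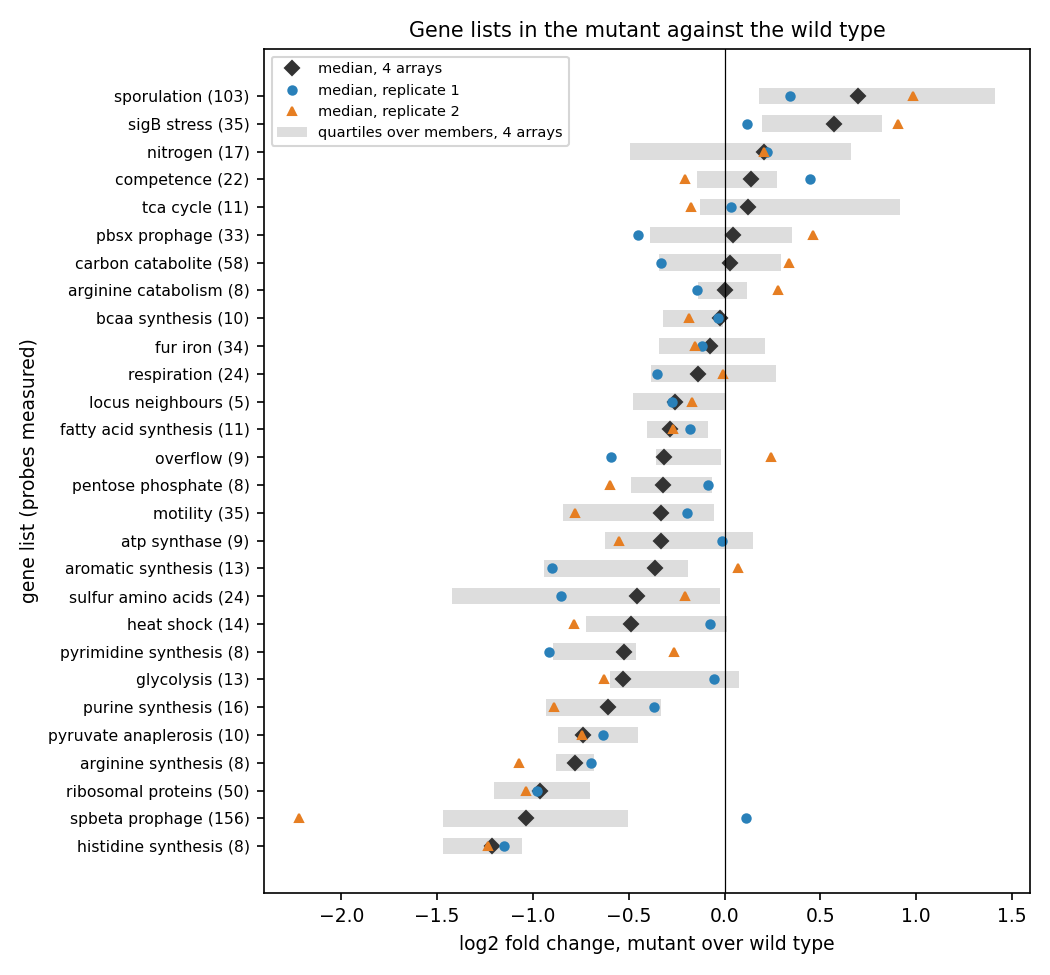
Median log2 fold change, mutant over wild type (horizontal axis), of each of the 28 tested gene lists (vertical axis, with the number of probes measured), over all 4 arrays (diamonds), in replicate 1 (circles) and in replicate 2 (triangles), with grey bars from the lower to the upper quartile of the members. Sporulation (0.69) and sigma B (0.57) lie highest and histidine synthesis (-1.22), SPβ (-1.04) and ribosomal proteins (-0.96) lowest, and the replicates lie far apart for SPβ.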

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

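No feature passed limma with Benjamini-Hochberg adjustment in the reported fit or in any of the 17 alternatives (0 calls each). In simulation the reported fit missed even 32-fold changes (0 of 200 recovered), so its count of 0 says little about how many genes changed. At an unadjusted p under 0.05 there were 28 features, against 210 with the replicate block, 18 with scaling to total signal, 12 without scaling and 14 to 97 when 1 array was left out. Alternatives added after the data were seen gave 162 for the block with cyclic loess and, with the mutant arrays crossed as in the value table's numbering, 5. The 210 with the block are not by themselves a sign of more changes, since 4.23% to 4.93% of simulated unchanged features had such a p there. gapB and pckA passed over the list alone in every alternative. Their folds and those of the deleted genes shrank where dim values were raised, in log2 from 5.33 to 4.16 and 3.69 for gapB, from -2.99 to -2.24 and -1.84 for ccpN and from -3.55 to -2.16 and -2.05 for ppsR with a floor at the 25th percentile and a pseudocount, and for pckA from 5.61 to 4.86 with a pseudocount. The deleted genes did not pass over the list alone with that crossed numbering (0 of 2 called), nor without wild-type replicate 2 (0 to 2 called over the arrays left out). Of the lists, 10 passed camera, against 4 to 8 when 1 array was left out, and 0 with an estimated correlation or with fry. The crossed numbering also ended the calls of pyruvate conversion (camera adjusted p = 0.0778), arginine synthesis (0.0616) and aromatic synthesis (0.0755). Sporulation and ribosomal proteins kept their calls in all 17 refits. Over all lists 28 calls were lost with the direction kept, 1 was lost with the direction reversed, and 10 were gained among 475 values. The sulfur amino acid list turned upward in camera without wild-type replicate 1, with a median still at -0.18 (-1.32 to -0.18 over the arrays left out). Of 1641 values of the 97 named probes under alternatives, 34, from 22 probes, had the other sign, but none was a call, and 0 of the 20 named by smallest unadjusted p in each direction changed sign. Directions of lists below the threshold turned 34 times. The block changed no other call than the 5 sporulation genes. The arginine breakdown list was not tested without the dimmest 25%, where too few members are left. A left-out array leaves 1 array in its strain, assumed to vary like the other strain. The smaller folds under a higher floor or a pseudocount follow from raising dim values; the other causes were not tested. Background on the arrays is unknown, so which handling of dim values is nearest to the true folds is open.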

Other observations

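Other genes with large differences that repeated in both replicates were picked out after their values were seen, and none passed limma's test over all features. The gene next to gapB, speD, which encodes S-adenosylmethionine decarboxylase, had log2 fold changes of 2.13 and 1.93 in replicates 1 and 2 (mean 2.03, SE 0.73), whereas nrdR, on the far side of speD from gapB, had 0.50 and 0.44, and metK near pckA had -0.22 and -0.18. Some genes of the killing systems that act early in sporulation were higher in both replicates, with 5.08 and 1.45 for skfA, which encodes the precursor of the killing factor, 3.57 and 1.80 for sdpR and 2.998 and 1.15 for sdpI, while skfE had 0.50 and -1.46 and skfF had -0.43 and -2.18. The dipeptide transport gene dppE had 2.76 and 1.56, against 0.15 and -0.65 for dppD. The germination genes gerM and gerQ had 2.20 and 2.77 and 2.29 and 1.82, and spoVIF had 2.37 and 2.17. Other germination genes are not given here, so these values do not speak for germination genes as a class. The nitrate reductase gene narG was lower, at -3.27 and -2.93 with mutant replicate 1 at the detection floor, but narH and narJ were not, at 0.44 and 0.18 and at 0.98 and 0.98.

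The array sets differed more than the strains. The SD over probes was 1.72 for the log2 difference between replicates 1 and 2 and 0.80 for that between strains. There were 40 probes at least 16-fold brighter on both replicate 1 arrays than on either replicate 2 array, 11 at least 16-fold brighter the other way, and 2 that differed at least 16-fold between the strains in the same sense. The probes of yetK, rimI, amyX and pbuX were at least 433-fold, 209-fold, 105-fold and 92.1-fold brighter in replicate 1, in both strains.

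In the weighing that follows, the tests within single array sets and the test of a missing prophage were chosen after the results were seen, and those against lists of matched brightness were fixed after the list medians but before the matched values were seen. The tests within single array sets and the test of a missing prophage pair the arrays as the single-sample files number them.

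Sporulation genes were higher in the mutant, with a median of 0.69. A rise of all dim probes on the mutant arrays is not enough, because the upper limit for random lists of the same brightness was 0.08. Both array sets went the same way, and the median of 0.34 in replicate 1, the smaller, lay above the upper limit of -0.02 for its own matched lists. The matched lists hold unrelated probes, so a list whose members vary together can pass their limits. SPβ did so upward in replicate 1 (0.11) and downward in replicate 2 (-2.22). With 1 array per strain in each set, these limits cannot show that a shift repeats. A candidate explanation is that some mutant cells had entered sporulation at harvest, whether from the mutation itself or from a later growth stage of those cultures. The design holds no other density or time point that would separate these, and both stay open.

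Ribosomal protein genes were lower in the mutant, with a median of -0.96. Random lists of the same brightness had a pooled median of -0.27, with a lower limit of -0.47, so brightness may account for a part only. Bright probes as a class were lower in replicate 2, with a matched median of -0.54, but hardly in replicate 1, with -0.02. In replicate 1 the ribosomal list had -0.98 against a lower limit of -0.14. The replicate 2 arrays, where the list stood out least from its matched lists, gave -1.03 against a lower limit of -0.74, so the pooled value did not come from a single array set. As for sporulation, the matched limits cannot show that the shift repeats. Slower growth of the mutant is a candidate explanation that was not tested, since no growth rates were analysed here.

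SPβ genes were lower in the mutant with a median of -1.04. With the numbering of the single-sample files, the shift of the list lay in a single array set. With the value table's numbering the list's median log2 intensity would be lower in both sets, at 12.16 against 12.97 and 13.38 against 14.58. The test of a lost prophage below was made for the former numbering only. In replicate 1 the median was 0.11, above the upper limit of -0.05 for matched lists. Loss of the prophage from the mutant would lower the bright SPβ probes in both sets, but the 73 on the list that were brighter than the array median on wild-type array 1 had a median of 0.12 there, and 1 of them, yorC, was at least 2-fold lower. With all 180 probes between the first and the last list member on the chromosome, 25 of them not on the list, 90 were that bright, with a median of 0.08, and 3 were at least 2-fold lower (bdbA, dpoL and yorC). In replicate 2, 113 of 124 such probes were at least 2-fold lower, with a median of -2.51. A difference between the cultures or arrays of that day may be the source of the list's shift, and prophage activity in its wild-type culture or loss of the prophage in its mutant culture alone was not tested.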
